A study of Schizosaccharomyces pombe with 8 samples.

How the data were processed

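RNA of the fission yeast Schizosaccharomyces pombe was sequenced from 8 libraries in 4 groups of 2. A wild-type strain (h- leu1-32 ura4-D18) and a strain labelled ∆wee1 (wee1::ura4+ in the same marker background) were each sampled untreated and after 15 min in 20 mM H2O2. Per the labels' protocols, cells came from mid-log cultures in rich medium (yeast extract with supplements), RNA was extracted with TRIzol, and libraries were made with the TruSeq stranded mRNA kit, which selects RNA with a poly(A) tail and keeps strand. Each library's group was taken from its title.

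Per the submitters' processing notes, the authors used cutadapt (a read trimmer), HISAT2 (a spliced aligner) and Cuffdiff (a program that estimates and compares transcript levels). Their versions, the genome build, the annotation release and the strand setting are not given in the sources used here. The authors' expression values are FPKM (fragments scaled by transcript length and by the mapped fragments of the library), deposited as 1 value per group, so that the 2 replicates of a group are already combined. The authors' deposited table of comparisons gives, for 7092 genes and 6 pairs of groups, a log2 fold change, a test statistic (a score), a p-value and a q-value, per the file headers. In that deposited table the lowest listed p-value is 5e-05, and q-values are adjusted over all 6 pairs together. The authors' fold changes equal the log2 ratio of the deposited FPKM values, read as the group named last over the group named first, and they were turned here so that H2O2 stands over untreated and ∆wee1 over wild type.

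The number of reads per library is unknown, since FPKM values combined over replicates keep no depth, and no interval or detection limit that needs depth was computed. No value per library was used, so a planned linear model across libraries (limma), leaving out single libraries and blocking by replicate number were replaced by the branch fixed for 1 value per group. In that branch a gene's change is the log2 ratio of the group values, each with a pseudocount of 1 FPKM, which understates changes of genes near that level. A gene is said to have risen, fallen or changed where the authors' deposited table lists it as significant at a q-value under 0.05. Groups of genes were summarised by their median log2 ratio and by its percentile among 10000 random lists of the same size, drawn from nuclear protein-coding genes in 20 bins of mean level. The members of a list were left among the genes drawn from. Some lists share members, so their medians are not independent. That percentile describes these pools and is not a p-value.

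An error for each log2 ratio was taken from the authors' deposited table: the fold change divided by its statistic gives the standard error that Cuffdiff used. Its squares added up over pairs of groups to within 1.48e-05 of their size in 6122 genes, so a variance per group could be solved and scaled to the pseudocount. Each ± below is this standard error. The authors' p-values are smaller than their listed statistics give on the normal curve, with a median normal deviate 1.42 times the statistic, so the errors printed here are the wider of the possible readings. The difference of the H2O2 response between genotypes was taken per gene as the difference of log2 ratios, and tested with a normal z test built from the group variances, with Benjamini-Hochberg adjustment over 6119 genes. On simulated data with 6119 genes and known changes, this z test of the response difference recovered 23% of changes of 1 log2 unit and 60% of changes of 2 units, and called 0.101% of unchanged genes. The simulated noise came from the same variances that the test divides by. In the data the z values had a robust SD of 0.456 rather than about 1, so the errors are too wide for most genes. The test is therefore stricter on the data than simulated, and a gene that does not pass is not shown to be unchanged. In the simulation of lists on the wild-type H2O2 ratios, 3.50% of unshifted lists of 20 genes fell outside the central 95% of random lists. There the ratios were permuted across genes and members drawn at random. The simulation therefore does not show how often lists of co-regulated genes would fall outside.

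Genes were measured if their mean over the 4 groups was at least 1 FPKM (6281 genes, of which 4949 were nuclear and protein-coding). The 24 gene lists, the rule for naming genes and the alternatives listed first were fixed before the data were examined. Named genes are the strain markers wee1, ura4 and leu1, then per comparison the 10 largest rises and 10 largest falls among the authors' calls. These needed a gene symbol in the files and at least 5 FPKM in the higher group. For each list described, up to 4 members with the largest absolute log2 ratio at that level were added, and ctt1, gpx1, hsp9, srx1, trr1, tpx1, pyp2, atf1, pap1, sty1, cdc2, cdc25, mik1 and cdc13 were always kept. Of the 229 genes so named, 137 lie in a locus that the authors' table shares with at least 1 other gene, and their values are less certain where the transcripts overlap. Alternatives were pseudocounts of 0.1 and 5 FPKM, minimum levels, quantile normalization, median centring, another adjustment of the p-values, a minimum fold and a limit to nuclear protein-coding genes.

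Coordinates are those of the deposited files, whose build is not named. Gene classes, names for genes listed by systematic ID alone, and neighbouring genes came from the RefSeq annotation of assembly ASM294v3, which matched 6737 of the 7092 IDs, and no coordinate of that assembly is printed. Sequence copies of genes were searched in the same assembly with blastn 2.17.0. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.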

Results

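Transcript levels were compared between a wild-type strain of the fission yeast Schizosaccharomyces pombe and a strain labelled ∆wee1, each untreated and after 15 min in 20 mM H2O2, a dose of peroxide that causes strong oxidative stress. Wee1 is a kinase that holds back entry into mitosis by phosphorylating the cell cycle kinase Cdc2. Each of the 4 groups had 2 libraries, and the files give 1 pooled FPKM value per gene and group, so no spread between replicates can be shown and the number of reads behind a value is unknown. Levels are given as pooled FPKM, changes as the log2 ratio of FPKM + 1 with ± the standard error implied by the authors' deposited table, and the words rose and fell are kept for genes that this table calls. The libraries of a group carry replicate numbers, but nothing in the labels says that they came from separate cultures, so the authors' tests may cover technical spread alone. Coordinates are those of the files, and the genome build is not given in the sources used here.

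The strain markers were examined first. The wee1 transcript (SPCC18B5.03, chromosome III, 721788 to 725835) stood at 8.91 FPKM in untreated wild type and 8.17 FPKM after H2O2, against 16.1 and 15.5 FPKM in the pools labelled ∆wee1. It was therefore higher under the deletion label, by 0.79 ± 0.22 untreated and 0.85 ± 0.22 after H2O2, and the authors' deposited table calls both differences. Because this goes against the label, the mutant pools are called the pools labelled ∆wee1 throughout, and every genotype direction below rests on that label. The ura4 gene (SPCC330.05c, chromosome III, 115589 to 116726), the marker inserted at wee1 per the labels and otherwise deleted in both strains (ura4-D18), stood at 0.131 and 0.0704 FPKM in wild type against 185 and 235 FPKM in the pools labelled ∆wee1. Its log2 ratios were 7.36 ± 1.55 untreated and 7.78 ± 1.75 after H2O2, which the authors' deposited table does not call, at q-values of 0.285 and 0.546. The leu1 gene, mutated in both strains per the labels, stood between 592 and 1044 FPKM in the 4 groups.

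RNAs that normally carry no poly(A) tail made up an uneven share of the pools. Ribosomal RNA genes held 3.13% of the summed FPKM in untreated wild type, 22.2% in wild type after H2O2, 10.8% in the untreated pool labelled ∆wee1 and 3.19% in that label after H2O2. The 22.2% counts as 0 another 4 measured ribosomal RNA genes, which had too many reads in that pool. A single gene, 5_8S_rRNA, held 2.62%, 12.1%, 9.65% and 2.72% of all FPKM in the same order of pools. The signal recognition particle RNA srp7 stood at 399, 16154, 778 and 303 FPKM in the same order. The mitochondrial ribosomal RNAs 21S_rRNA and 15S_rRNA and the mitochondrially encoded cox1, cox2 and cox3 also had their highest level in the wild-type H2O2 pool. Nuclear protein-coding genes held 73.2% of the FPKM in that pool, against 95.1% in untreated wild type.

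**Figure D1:**
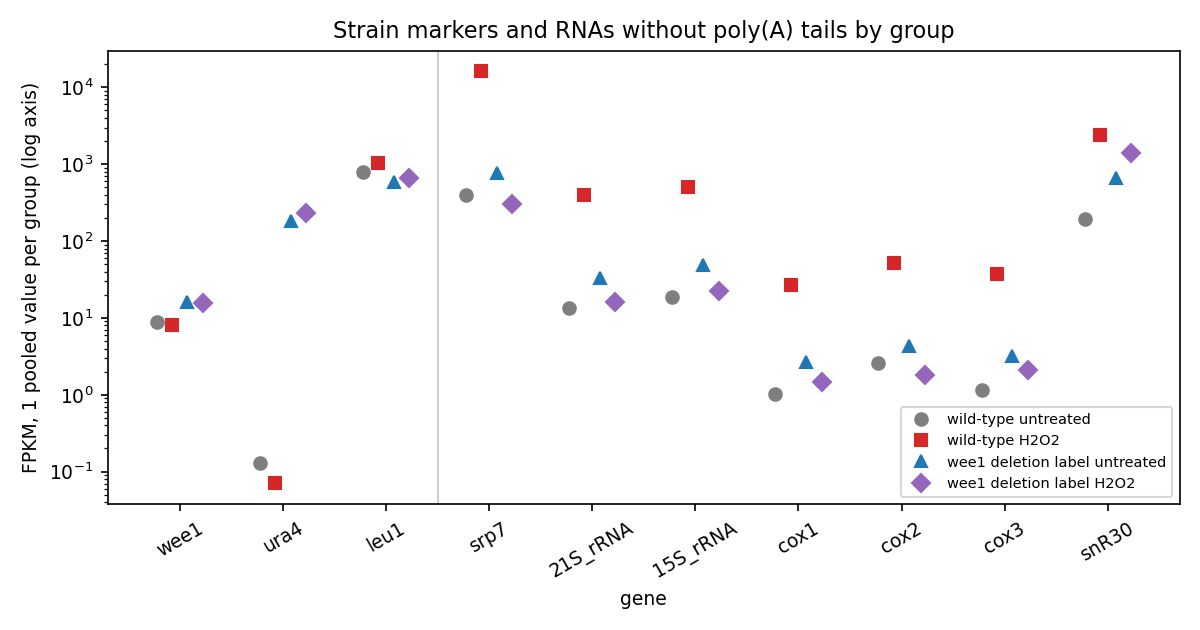
Pooled FPKM per group (log axis) of the strain markers wee1, ura4 and leu1 and of RNAs without poly(A) tails, with 1 point per group and no error bar, since replicates were combined in the files. The wee1 points labelled ∆wee1 (16.1 and 15.5 FPKM) lie above the wild-type points, and srp7 reaches 16154 FPKM in the wild-type H2O2 pool alone.

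The first comparison asked how wild-type cells changed after 15 min of H2O2. Several genes that remove peroxide rose, led by srx1, the sulfiredoxin that repairs over-oxidised peroxiredoxin (SPBC106.02c, chromosome II, 376253 to 377036), which went from 20.6 to 363 FPKM (4.07 ± 0.72). With it rose ctt1, the catalase (1.29 ± 0.22), gpx1, a glutathione peroxidase (1.0 ± 0.24), tpx1, the main peroxiredoxin (0.87 ± 0.25), and trx1, a thioredoxin (0.91 ± 0.24). Most hexose transporters fell, and ght5, which takes up glucose, went from 669.7 to 135 FPKM (-2.30 ± 0.22). The mating transcription factor ste11 fell from 20.1 to 3.64 FPKM (-2.19 ± 0.23). The authors' deposited table calls 906 of 6277 tested genes, 437 up and 469 down. Of these calls in the authors' deposited table, nuclear protein-coding genes made up 318 of those up and 451 of those down.

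Targets of the stress kinase Sty1 and its transcription factor Atf1 had a median log2 ratio of 0.50 over 17 genes, where the central 95% of matched random lists spanned -0.04 to 0.27. The authors' deposited table has 8 of them up and 1 down (11 and 1 adjusted over the list alone). Among them lsd90 (1.63 ± 0.22), ish1, a nuclear envelope stress protein (1.59 ± 0.38), and pyp2, the phosphatase that turns Sty1 off (1.35 ± 0.29), rose, while cmk1, a calmodulin-dependent kinase, fell (-1.38 ± 0.23). Levels of hsp9 (0.06 ± 0.25) and of fbp1 (-1.57 ± 0.83) were not called. Of 12 genes driven by Pap1, the AP-1-like factor of the antioxidant response, the median was 0.61. The authors' deposited table has 6 up and 0 down (7 and 0 adjusted over the list alone). Those that rose included the drug exporters caf5 (1.30 ± 0.25) and bfr1 (0.90 ± 0.20). The transcripts of the regulators themselves were not called, at 0.38 ± 0.34 for sty1, 0.17 ± 0.21 for atf1 and -0.03 ± 0.21 for pap1.

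Chaperones had a median of 0.54 over 20 genes, a direction that turned to -0.04 under quantile normalization. The authors' deposited table has 9 of them up and 0 down (11 and 0 adjusted over the list alone). The small heat shock proteins hsp16 (1.18 ± 0.24) and hsp20 (1.18 ± 0.33), the DnaJ-type protein psi1 (1.19 ± 0.23) and the Hsp90 partner cdc37 (1.24 ± 0.44) rose. Outside this list hsp3101, of the DJ-1 family, rose from 12.6 to 168 FPKM (3.64 ± 0.40). The ribosome biogenesis list, which also holds RNA polymerase I subunits and the cell cycle gene nuc2, had a median of 0.35 over 55 genes. The authors' deposited table has 15 up and 0 down (23 and 0 adjusted over the list alone), and the rises included imp4 (1.53 ± 0.25) and nop16 (1.12 ± 0.22). The respiratory list had a median of 0.27, which became -0.09 under quantile normalization. The authors' deposited table has 12 of its 57 genes up (13 adjusted over the list alone). Among its largest rises were the mitochondrially encoded cox1 (3.77 ± 0.32), cox2 (3.90 ± 0.41) and cox3 (4.14 ± 0.40), in the pool where ribosomal RNA held 22.2% of FPKM. Without the mitochondrially encoded members its median was 0.23, inside the central 95% of random lists.

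Hexose transporters had a median of -1.29 over 8 genes. The authors' deposited table has 5 down and 1 up, with the same counts adjusted over the list alone. Beside ght5, ght1 fell from 20.6 to 1.12 FPKM (-3.34 ± 0.44), and ght8 (-1.39 ± 0.23) and ght4 (-1.37 ± 0.33) also fell. Outside this list the invertase inv1 (-2.14 ± 0.24), the glucose-6-phosphate dehydrogenase paralog zwf2 (-2.24 ± 0.25) and the amino acid permease isp5 (-1.88 ± 0.67) fell. So did the calcineurin-responsive transcription factor prz1 (-1.99 ± 0.27), pun1 (-2.52 ± 0.37) and mug14 (-2.22 ± 0.45), whereas zwf1, the main glucose-6-phosphate dehydrogenase, rose (0.73 ± 0.25). The non-coding RNA prl21 went from 6.70 FPKM to being listed at 0.

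Many cell cycle genes fell in wild type. Transcripts made in mitosis and at the M-G1 boundary had a median of -0.63. The authors' deposited table has 10 of 19 down and 0 up (15 and 0 adjusted over the list alone). The falls included the septum glucanase agn1 (-0.96 ± 0.24), the cell separation genes adg1 (-1.34 ± 0.26) and adg2 (-0.85 ± 0.21), and the kinesin klp6 (-0.97 ± 0.24). Targets of the G1/S factor MBF had a median of -0.32. The authors' deposited table has 5 of 18 down (7 adjusted over the list alone), such as the replication licensing factor cdc18 (-1.03 ± 0.31), the MBF corepressor nrm1 (-0.85 ± 0.42) and tos4 (-0.82 ± 0.30). The 19 regulators of Cdc2 had a median of -0.40. The authors' deposited table has 5 down and 1 up (8 and 1 adjusted over the list alone). Those that fell included cdc25, the phosphatase that opposes Wee1 (-0.74 ± 0.22), the cyclin cdc13 (-0.50 ± 0.22), the Cdc2 inhibitor rum1 (-0.66 ± 0.23) and the phosphatase clp1 (-0.71 ± 0.27). Neither mik1, a kinase related to Wee1 (-0.49 ± 0.26), nor cdc2 (-0.21 ± 0.25) was called. Histone transcripts had a median of -0.18 over 11 genes, below the 0.16 to 0.34 of matched random lists, and none was called.

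The other lists stayed inside the central 95% of random lists. The authors' deposited table has 9 of 26 antioxidant and glutathione enzymes, 5 of 131 ribosomal proteins, 3 of 21 stress pathway genes, 3 of 31 DNA damage genes and 2 of 34 proteasome genes up, with 1 stress pathway gene and 1 DNA damage gene down. Among those up was the recombination gene rad54 (0.84 ± 0.23). For these lists the counts adjusted over the list alone were 9, 1, 3, 3 and 2 up, and again 1 and 1 down. The authors' deposited table has 0 up and 2 down of 24 autophagy genes, 1 and 2 of 7 phosphate genes and 3 and 3 of 25 mating and meiosis genes. Adjusted over the list alone these were 0 and 1, 1 and 2, and 3 and 3 in the authors' deposited table. Iron and copper uptake genes also went both ways. The authors' deposited table has 2 up and 3 down of 15 (2 and 4 adjusted over the list alone), as frp1, a ferric reductase, fell (-1.29 ± 0.29). Quantile normalization moved the median of nuclear protein-coding genes from -0.03 to -0.15 and turned the sign of the ribosomal protein median (0.29 to -0.11) and of the glycolysis median (0.21 to -0.23). Counting only changes of at least 2-fold left 322 of the calls in the authors' deposited table, 203 up and 119 down.

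The second comparison asked the same of the pools labelled ∆wee1. Among called genes with a symbol the largest rises were those of srx1 (45.3 to 736 FPKM, 3.99 ± 0.57) and hsp3101 (3.04 ± 0.28), followed by prl65 (2.78 ± 0.26), lsd90 (2.64 ± 0.22) and the catalase ctt1, which went from 107 to 515 FPKM (2.26 ± 0.22). The largest falls among them were those of the hexose transporter ght1 (-2.81 ± 0.39), the glycerol dehydrogenase gld1 (-2.25 ± 0.40) and zwf2 (-2.20 ± 0.26). The authors' deposited table calls 598 of 6312 tested genes, 337 up and 261 down.

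Sty1-Atf1 targets had a median of 0.98 in this label. The authors' deposited table has 13 up and 2 down of 17 (13 and 3 adjusted over the list alone). Beside lsd90 and ctt1, pyp2 (1.85 ± 0.30), ish1 (1.80 ± 0.36), gpx1 (1.09 ± 0.24) and atf1 itself (0.59 ± 0.20) rose. Pap1 targets had a median of 0.63. The authors' deposited table has 8 up and 1 down (9 and 1 adjusted over the list alone), and the rises included caf5 (1.31 ± 0.25), tpx1 (1.0 ± 0.25) and the thioredoxin reductase trr1 (0.86 ± 0.29). Antioxidant and glutathione enzymes had a median of 0.34 and chaperones of 0.47. The authors' deposited table has 10 of 26 antioxidant genes up (13 adjusted over the list alone) and 8 of 20 chaperones up (10 adjusted over the list alone). Among the chaperones psi1 (1.09 ± 0.23), the Hsp70 ssa1 (0.87 ± 0.27), hsp20 (0.77 ± 0.33) and sti1 (0.73 ± 0.23) rose. The ribosome biogenesis list had a median of 0.15. The authors' deposited table has 5 of 55 up (4 adjusted over the list alone), among them bms1 (0.79 ± 0.21) and imp4 (0.77 ± 0.23).

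Many cell cycle genes fell in this label too. M and M-G1 transcripts had a median of -0.51. The authors' deposited table has 8 of 19 down (14 adjusted over the list alone), such as adg1 (-1.01 ± 0.22) and agn1 (-0.90 ± 0.24). MBF targets had a median of -0.40. The authors' deposited table has 6 of 18 down (7 adjusted over the list alone), such as cdc18 (-0.91 ± 0.25), the replication factor cdt1 (-0.82 ± 0.24) and the checkpoint mediator mrc1 (-0.87 ± 0.24). Cdc2 regulators had a median of -0.25, inside the random lists, and the authors' deposited table has 6 down and 2 up (6 and 2 adjusted over the list alone). Among them mik1 fell (-0.65 ± 0.25) and the phosphatase pyp3 rose (0.92 ± 0.22), while cdc25 (-0.25 ± 0.23) and cdc13 (-0.31 ± 0.22) were not called. Histones had a median of -0.07, below the 0.04 to 0.22 of random lists, and none was called.

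Hexose transporters had a median of -0.89. The authors' deposited table has 5 down and 1 up of 8, with the same counts adjusted over the list alone. The falls included ght4 (-1.56 ± 0.32), ght5 (1316 to 534 FPKM, -1.30 ± 0.25) and ght3 (-1.02 ± 0.24). Iron and copper uptake genes had a median of -0.24. The authors' deposited table has 5 down and 1 up of 15 (6 and 1 adjusted over the list alone), as frp1 (-1.23 ± 0.25), the iron permease fip1 (-0.97 ± 0.23) and its partner oxidase fio1 (-0.96 ± 0.25) fell. With a pseudocount of 5 FPKM this list no longer stood outside the random lists. The ammonium transporter amt1 (-1.40 ± 0.26), the peptide transporter ptr2 (-1.34 ± 0.61), urg2 (-1.35 ± 0.25), mug14 (-1.49 ± 0.37) and mug108 (-1.35 ± 0.34) fell. The enolase eno102 (1.68 ± 0.31), tms1 (1.78 ± 0.39) and the nucleolar RNA snoR61 (1.76 ± 0.28) rose. The signal recognition particle RNA srp7 fell in this label (-1.36 ± 0.34), where ribosomal RNA held 10.8% of FPKM untreated and 3.19% after H2O2. Counting only changes of at least 2-fold left 217 of the calls in the authors' deposited table, 164 up and 53 down.

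The responses of both strains overlapped. Among 6195 genes tested in both, the authors' deposited table has 227 genes up in both. The authors' deposited table has 431 of them up in wild type and 332 in the pools labelled ∆wee1, and independent lists of these sizes would share 23.1. The authors' deposited table has 198 genes down in both, of 468 and 258, against 19.5 for independent lists. The authors' deposited table has 6 genes up in wild type and down in the other label, and 1 the other way round. Across 4949 nuclear protein-coding genes, which are not independent replicates, the log2 ratios had a Pearson r of 0.756 and a Spearman rho of 0.777.

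**Figure D2:**
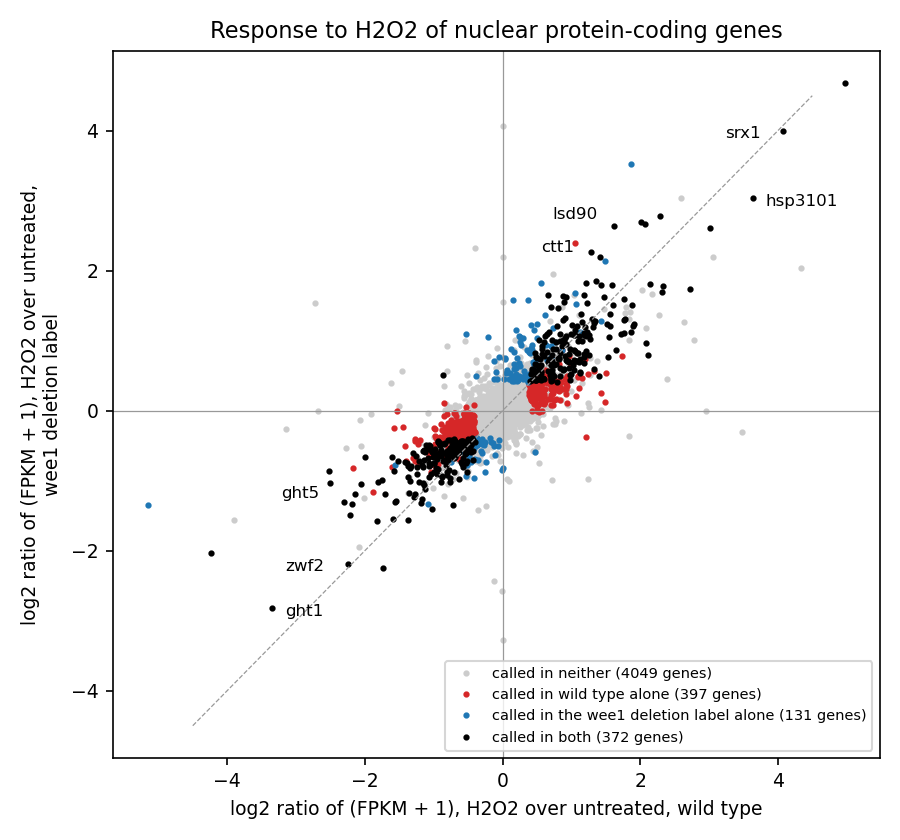
Log2 ratio of FPKM + 1 after H2O2 over untreated, in wild type (horizontal) and in the pools labelled ∆wee1 (vertical), with 1 point per measured nuclear protein-coding gene, coloured by the calls of the authors' deposited table, and the dashed line where both are equal. The authors' deposited table calls 372 of these genes in both, 397 in wild type alone and 131 in the ∆wee1 label alone, and lsd90 and ctt1 lie above the dashed line.

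The third comparison set the untreated pool labelled ∆wee1 against untreated wild type. Genes of cell division were higher in that label, such as adg2 (52.2 to 194 FPKM, 1.87 ± 0.21) and cdt2, which marks replication proteins for destruction (1.75 ± 0.22). The iron uptake genes fio1 (1.90 ± 0.26) and str1, a siderophore transporter (1.74 ± 0.22), rose, while the phosphate genes pho1, an acid phosphatase (269 to 53.7 FPKM, -2.30 ± 0.21), and pho84, a phosphate transporter (-2.01 ± 0.22), fell. The authors' deposited table calls 557 of 6292 tested genes, 292 higher and 265 lower under the ∆wee1 label, whose own wee1 level was higher.

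M and M-G1 transcripts had a median of 0.71. The authors' deposited table has 13 of 19 higher and 0 lower (14 and 0 adjusted over the list alone), and those higher included the septin-binding mid2 (1.27 ± 0.24) and cfh4 (0.97 ± 0.36). MBF targets had a median of 0.55. The authors' deposited table has 8 of 18 higher (10 adjusted over the list alone), among them the ribonucleotide reductase cdc22 (1.05 ± 0.22), the replication protein A subunit ssb1 (1.10 ± 0.21) and the polymerase delta subunit cdm1 (1.63 ± 0.74). Histones had a median of 0.48. The authors' deposited table has 4 of 11 higher (7 adjusted over the list alone), including hht1 (0.72 ± 0.24), htb1 (0.70 ± 0.26) and the H2A.Z gene pht1 (0.75 ± 0.21). Values of single histone genes with near-identical copies are uncertain. The Cdc2 regulators went both ways. The authors' deposited table has 3 higher and 2 lower (3 and 2 adjusted over the list alone), with slp1, which activates the anaphase-promoting complex (0.94 ± 0.41), the polo kinase plo1 (0.74 ± 0.22) and wee1 higher, and cdc25 lower (20.4 to 12.3 FPKM, -0.69 ± 0.22). The median of that list was 0.10, inside the range of random lists, and mik1 (0.42 ± 0.24), cdc13 (0.13 ± 0.22) and cdc2 (-0.20 ± 0.25) were not called.

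Cytoplasmic ribosomal proteins had a median of -0.41 over 131 genes (-0.11 under quantile normalization). Matched random lists, which could hold ribosomal proteins themselves, spanned -0.35 to -0.25. The authors' deposited table has 36 lower and 0 higher (77 and 0 adjusted over the list alone), such as rps2202 (-1.01 ± 0.22) and rpl102 (-0.70 ± 0.23). The ribosome biogenesis list went the other way, with a median of 0.16. The authors' deposited table has 8 of 55 higher (8 adjusted over the list alone), such as imp4 (0.82 ± 0.26) and rrp14 (0.76 ± 0.27). Proteasome genes had a median of 0.29 with 5 of 34 higher in the authors' deposited table (5 adjusted over the list alone), including rpt2 (0.47 ± 0.21). Sty1-Atf1 targets had a median of 0.20. The authors' deposited table has 4 higher and 1 lower (6 and 2 adjusted over the list alone). The metallothionein zym1 (1.79 ± 0.25), lsd90 (1.67 ± 0.22) and hsp9 (1.24 ± 0.26) were among those higher, and ctt1 was lower (-0.73 ± 0.21). Chaperones had a median of 0.10. The authors' deposited table has 5 of 20 higher (6 adjusted over the list alone), including ssa1 (1.12 ± 0.25) and hsp16 (1.02 ± 0.24). Under quantile normalization the list no longer stood outside the random lists.

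Phosphate acquisition genes had a median of 0.04, inside the random lists, and beside pho1 and pho84 none was called. The authors' deposited table has 2 lower and 0 higher of 7, with the same counts adjusted over the list alone. Iron and copper uptake genes had a median of 0.09, inside the random lists. The authors' deposited table has 6 higher and 3 lower of 15 (6 and 3 adjusted over the list alone). The transporter str3 (1.82 ± 0.30) and fip1 (1.72 ± 0.25) were higher, and the copper transporter ctr4 fell (314 to 127 FPKM, -1.30 ± 0.21). Of the hexose transporters ght3 (2.29 ± 0.26) and ght5 (0.97 ± 0.25) were higher and ght8 was lower (-0.58 ± 0.24). The authors' deposited table has 3 higher and 1 lower of 8 (4 and 1 adjusted over the list alone). Their median was 0.34, and 0.11, inside the random lists, when members under a mean of 5 FPKM were left out. Also higher were prl65 (3.01 ± 0.44) and the nucleolar RNA snR30 (1.78 ± 0.55). Lower were the biotin transporter vht1 (-1.57 ± 0.32), the pheromone precursor mfm2 (-1.53 ± 0.27), ste11 (-1.11 ± 0.22) and the MBF partner rep2 (-1.33 ± 0.41). The same held for the cell surface gene pfl3 (-1.40 ± 0.22), abp2 (-1.41 ± 0.39), prl3 (-1.86 ± 0.69) and urg2 (-1.26 ± 0.21). The autophagy list (median 0.20) and the respiratory list (median 0.15) stood above the random lists. The authors' deposited table has 0 and 1 of their members higher (0 and 0 adjusted over the list alone). Counting only differences of at least 2-fold left 172 of the calls in the authors' deposited table, 110 higher and 62 lower.

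Several of the largest rises of genes with a symbol in the ∆wee1 label lay in runs of neighbouring genes near chromosome ends. The enolase eno102 (SPBPB21E7.01c, chromosome II, 58136 to 59704) went from 2.83 to 31.1 FPKM (3.07 ± 0.48), the heme-binding protein shu1 (SPAC1F8.02c, chromosome I, 85566 to 86324) from 0.545 to 11 FPKM (2.96 ± 0.43), and the methyltransferase gene pcm2 (SPAC869.08, chromosome I, 5497918 to 5499280) from 1.36 to 12.6 FPKM (2.52 ± 0.33). The transporter ght3 lies beside shu1, and mel1, an alpha-galactosidase (0.312 to 4.98 FPKM), beside pcm2. In the opposite direction gdt1, named after its values were seen, at the same end of chromosome I as pcm2 (I, 5540032 to 5541502), stood at 83 FPKM in wild type and 1.24 FPKM in the pool labelled ∆wee1.

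**Figure D3:**
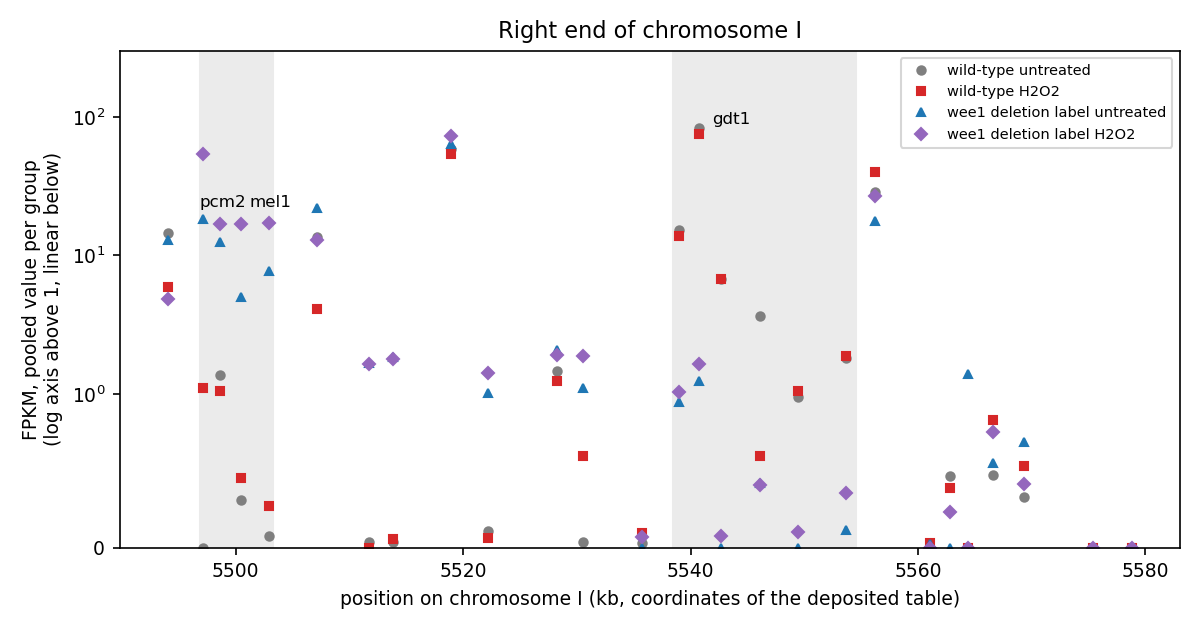
Pooled FPKM per group (log axis above 1, linear below) of genes at the right end of chromosome I against their position in the coordinates of the files, with 1 point per gene and group, no error bars since replicates were combined, and shading over the runs at least 4-fold apart between the labels. The pcm2 run is higher in the pools labelled ∆wee1 and the gdt1 run is higher in wild type (83 against 1.24 FPKM untreated for gdt1). The 4-fold limit was applied per gene to FPKM summed over both conditions.

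The fourth comparison set the H2O2 pool labelled ∆wee1 against the wild-type H2O2 pool. Division genes were higher, with adg2 at 2.12 ± 0.21, mid2 at 1.30 ± 0.25 and the septum glucanase eng1 at 1.28 ± 0.22. The stress genes lsd90 (59.3 to 386 FPKM, 2.68 ± 0.22) and zym1 (2.32 ± 0.24) rose. Of the 10 largest falls among called genes with a symbol, all but that of ecl3 were of RNAs without poly(A) tails that stood high in the wild-type H2O2 pool: srp7 (-5.73 ± 0.32), 21S_rRNA (-4.54 ± 0.28), 15S_rRNA (-4.41 ± 0.28), cox1 (-3.50 ± 0.32), cox2 (-4.24 ± 0.41), cox3 (-3.63 ± 0.40), cob1 (-4.06 ± 1.17), atp6 (-2.37 ± 0.44) and the spliceosomal snu2 (-3.79 ± 0.99). The authors' deposited table calls 856 of 6333 tested genes, 412 higher and 444 lower under the ∆wee1 label, whose own wee1 level was higher. Of these calls in the authors' deposited table, nuclear protein-coding genes made up 372 of the higher and 349 of the lower. Under quantile normalization 435 of all the calls were higher and 421 lower.

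M and M-G1 transcripts had a median of 0.75, MBF targets of 0.57 and histones of 0.69. The authors' deposited table has 14 of 19, 6 of 18 and 6 of 11 of them higher (16, 7 and 7 adjusted over the list alone). Their members cfh4 (0.99 ± 0.42), cdt2 (1.28 ± 0.21), ssb1 (1.24 ± 0.21), cdc22 (1.19 ± 0.22), hht1 (0.90 ± 0.23) and htb1 (0.84 ± 0.25) rose. Cdc2 regulators had a median of 0.35. The authors' deposited table has 6 higher and 1 lower of 19 (7 and 1 adjusted over the list alone), those higher including slp1 (0.95 ± 0.47) and plo1 (0.64 ± 0.22), while cdc25 (-0.20 ± 0.23) and mik1 (0.25 ± 0.26) were not called.

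Sty1-Atf1 targets had a median of 0.50. The authors' deposited table has 7 of 17 higher and 0 lower (8 and 0 adjusted over the list alone), including hsp9 (1.38 ± 0.27), gpx1 (0.60 ± 0.24) and atf1 (0.69 ± 0.20), while ctt1 (0.24 ± 0.23) and pyp2 (0.16 ± 0.25) were not called. Pap1 targets had a median of 0.20. The authors' deposited table has 3 higher and 2 lower (4 and 2 adjusted over the list alone). In this list srx1 (363 to 736 FPKM, 1.02 ± 0.34) and the glutathione transferases gst2 (0.73 ± 0.23) and gst3 (0.77 ± 0.27) rose, and the drug exporter pmd1 fell (-0.62 ± 0.20). Chaperones had a median of 0.09, antioxidant and glutathione enzymes of 0.16 and stress pathway genes of 0.22, each above the random lists. The authors' deposited table has 4, 4 and 3 of their members higher (4, 4 and 6 adjusted over the list alone), and 1 antioxidant gene lower (1 adjusted over the list alone). The stress pathway list fell inside the random lists with a pseudocount of 0.1 FPKM, and so did the stress pathway and Pap1 lists when genes under a mean of 5 FPKM were left out. The chaperones that rose included ssa1 (0.96 ± 0.27) and hsp16 (0.52 ± 0.25). The chaperone, antioxidant and stress pathway lists share members with the Sty1-Atf1 and Pap1 lists, such as hsp9, srx1 and atf1, so they are not separate results. Autophagy genes had a median of 0.32 and proteasome genes of 0.26. The authors' deposited table has 5 of 24 autophagy genes higher (5 adjusted over the list alone), such as atg8 (0.81 ± 0.30) and the kinase atg1 (0.68 ± 0.25). The authors' deposited table has 3 of 34 proteasome genes higher (3 adjusted over the list alone), such as rpn2 (0.46 ± 0.22).

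Cytoplasmic ribosomal proteins had a median of -0.54, where matched random lists spanned -0.50 to -0.40. These random lists could hold ribosomal proteins themselves, so they cannot show whether other genes of that level were lower too. Under quantile normalization the median of the ribosomal proteins became 0.00. The authors' deposited table has 86 of 131 lower and 0 higher (120 and 0 adjusted over the list alone), such as rps2202 (-0.97 ± 0.22) and rps1402 (-0.80 ± 0.26). Hexose transporters had a median of 0.51, or 0.28 and inside the random lists with a pseudocount of 5 FPKM. The authors' deposited table has 3 higher and 2 lower of 8 (3 and 2 adjusted over the list alone). Of these ght5 stood at 135 against 534 FPKM (1.98 ± 0.22) and ght3 was higher (2.47 ± 0.28). The genes of the chromosome-end runs were again among the largest rises, with eno102 at 3.68 ± 0.39, mel1 at 3.62 ± 0.70, pcm2 at 3.12 ± 0.32 and shu1 at 2.92 ± 0.45, as were prl65 (3.51 ± 0.29) and the galactose enzyme gal10 (2.01 ± 0.35). The phosphate genes pho1 (-1.98 ± 0.22) and pho84 (-1.41 ± 0.24), and ecl3, a small protein linked to chronological lifespan (-2.64 ± 0.83), were lower. The phosphate acquisition list had a median of 0.07, inside the random lists. The authors' deposited table has 1 higher and 2 lower of its 7 genes, with the same counts adjusted over the list alone, and pho7 was the higher one (0.71 ± 0.24). Iron and copper uptake genes had a median of 0.08, inside the random lists. The authors' deposited table has 6 higher and 4 lower of 15 (6 and 5 adjusted over the list alone), with str1 (1.53 ± 0.21) and fip1 (1.38 ± 0.27) among those higher. Ribosomal RNA held 22.2% of FPKM in the wild-type H2O2 pool and 3.19% in the other, and quantile normalization turned the sign of the glycolysis median (-0.27 to 0.25). Counting only differences of at least 2-fold left 236 of the calls in the authors' deposited table, 124 higher and 112 lower.

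Genotype differences untreated and after H2O2 overlapped. The authors' deposited table has 185 genes higher under the ∆wee1 label in both (287 untreated and 411 after H2O2), against 18.9 for independent lists among 6231 genes. The authors' deposited table has 186 lower in both (264 and 440, against 18.6). The authors' deposited table has 9 genes higher untreated and lower after H2O2, and 1 the other way round. Across 4949 nuclear protein-coding genes the log2 ratios had a Pearson r of 0.759 and a Spearman rho of 0.706.

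**Figure D4:**
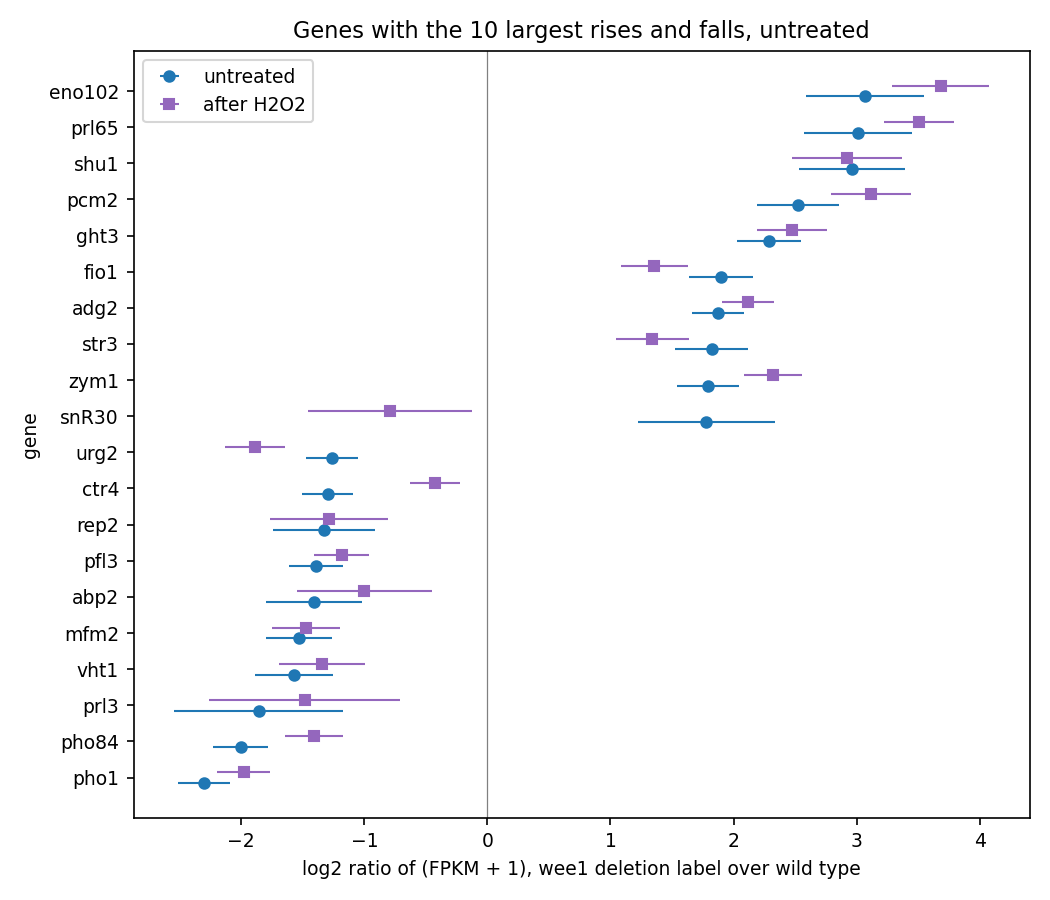
Log2 ratio of FPKM + 1, pools labelled ∆wee1 over wild type, untreated (circles) and after H2O2 (squares), for the 10 largest rises and 10 largest falls of the untreated comparison, with bars of 1 standard error on either side as implied by the authors' deposited table. Of these genes snR30 alone has ratios of opposite sign in the pair of conditions (1.78 untreated and -0.79 after H2O2).

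The last comparison asked which genes responded to H2O2 differently under the ∆wee1 label. Sty1-Atf1 targets had higher H2O2 ratios there, in 17 of 17 genes, with a median difference of 0.42, against -0.14 to 0.05 for the central 95% of random lists. The difference was 1.02 ± 0.31 for lsd90, 0.98 ± 0.31 for ctt1 and 0.42 ± 0.29 for atf1, and these genes did not pass the z test, with adjusted p-values of 0.239 for lsd90 and 0.356 for ctt1. With variances scaled to the authors' p-values, a choice made after the data were seen, the adjusted p of the z test was 6.67e-04 for lsd90 and 0.00172 for ctt1. For ctt1, which was lower in the untreated pool labelled ∆wee1 (107 against 178 FPKM), the levels after H2O2 were 515 and 435 FPKM.

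By size alone 246 of 5862 genes differed by at least 1 log2 unit, 80 higher and 166 lower in the ∆wee1 label. Of the higher ones 4 are ribosomal RNA genes listed at 0 FPKM in the wild-type H2O2 pool and marked in the authors' deposited table as having too many reads, so their difference is not a measured one. Among nuclear protein-coding genes alone the balance was the other way, with 36 higher and 22 lower of 4784. The z test with Benjamini-Hochberg adjustment passed 19 of 6119 genes (94 at an unadjusted p under 0.05), mostly RNAs without poly(A) tails. The 3 nuclear protein-coding genes among them, named after their values were seen, were cmt2 (1.47 ± 0.36, adjusted p of the z test 0.0150), SPAC2H10.01 (1.37 ± 0.29, adjusted p of the z test 0.00105) and rnh203, a ribonuclease H2 subunit (-3.79 ± 1.0, adjusted p of the z test 0.0459). The gene cmt2 lies in a run near an end of chromosome II that was higher in the pools labelled ∆wee1. Its log2 ratio after H2O2 was negative in both strains, at -2.50 in wild type and -1.04 under the ∆wee1 label. SPAC2H10.01 fell in wild type (-0.86) and rose under the ∆wee1 label (0.51). With the scaled variances 56 genes passed, 31 of them nuclear protein-coding. Of these 23 had higher and 8 lower ratios under the ∆wee1 label, and over all classes 23 and 33. Those with higher ratios under the ∆wee1 label included ght5 (1.0 ± 0.34), ste11 (0.85 ± 0.33), inv1 (0.94 ± 0.33), prz1 (1.33 ± 0.39), pun1 (1.65 ± 0.46) and gal10 (1.22 ± 0.44). Each gene named in that sentence had a negative ratio after H2O2 in both strains, nearer to none under the ∆wee1 label. For ght5 the ratios were -2.30 in wild type and -1.30 under that label. Those with lower ratios, named after their values were seen, included bsu1 (-1.12 ± 0.38), fes1 (-0.92 ± 0.34), puf5 (-0.84 ± 0.30) and zpr1 (-0.78 ± 0.31). Ratios of bsu1, fes1 and zpr1 were positive in both strains, while that of puf5 was -0.01 in wild type and -0.85 under the ∆wee1 label.

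The ribosome biogenesis list had lower H2O2 ratios under the ∆wee1 label, with a median difference of -0.20 and 48 of 55 genes lower. Histones (0.13), antioxidant and glutathione enzymes (0.02), iron and copper uptake genes (-0.14) and the respiratory list (-0.11, or 0.02 under quantile normalization) also had median differences outside the random lists. Of these the antioxidant list under quantile normalization, the iron list without members under a mean of 5 FPKM, and the respiratory list without its mitochondrially encoded members fell inside them. Over 178 nuclear protein-coding genes that rose in both strains the median log2 ratio was 0.95 in wild type and 0.86 in the other label. Over 193 that fell in both it was -0.81 and -0.63.

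**Figure D5:**
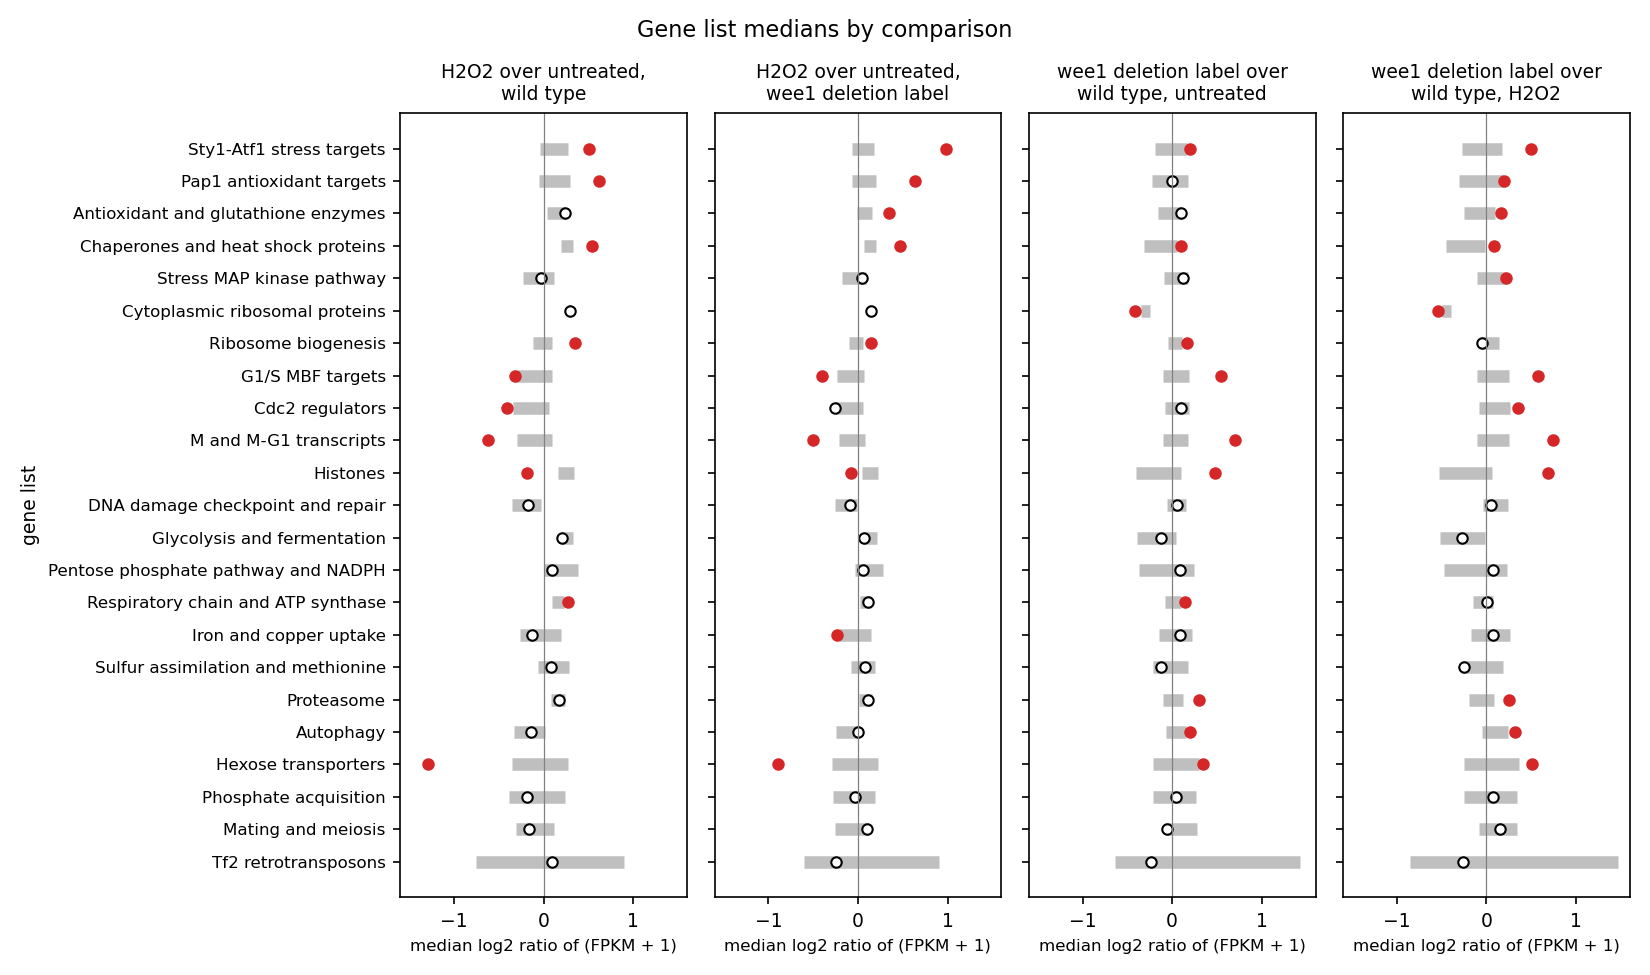
Median log2 ratio of FPKM + 1 of 23 gene lists (points) in each of 4 comparisons, with grey bars for the central 95% of 10000 random lists matched on level, and filled red points where the median lies outside. Sty1-Atf1 targets lie at 0.50 after H2O2 in wild type and 0.98 in the pools labelled ∆wee1, and M and M-G1 transcripts at 0.71 and 0.75 for the ∆wee1 label over wild type, while under quantile normalization the chaperone and respiratory medians in wild type turn to -0.04 and -0.09, and the ribosomal protein median under H2O2 to 0.00.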

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

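The z test of the difference in H2O2 response and every test of an explanation in this part were chosen after the results were seen. By that z test with Benjamini-Hochberg adjustment, the H2O2 response of 19 of 6119 genes differed between the genotype labels. The values that follow are the log2 ratio after H2O2 in the pools labelled ∆wee1 minus that in wild type. A negative value is a lower ratio under the ∆wee1 label.

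The ribosomal RNAs 21S_rRNA (-5.75), 15S_rRNA (-5.73), SPRRNA.45 (-5.18), SPRRNA.52 (-5.81) and 5_8S_rRNA (-4.63) had lower responses. So did the mitochondrially encoded cox1 (-4.34), cox2 (-4.81), cox3 (-4.60) and SPMIT.06 (-5.60). Among small RNAs the values were -6.70 for srp7, -8.34 for snu1, -5.58 for snu2, -4.65 for snR5, -5.04 for Fungi_U3 and -2.32 for S_pombe_snR99. The non-coding RNA SPNCRNA.757 stood at -2.46.

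Most of these RNAs carry no poly(A) tail and stood high in the wild-type H2O2 pool, a pattern with a technical and a biological reading. The genes weighed here were at least 4-fold higher after H2O2 in wild type and listed above 0 FPKM in at least 1 pool labelled ∆wee1. For 25 ribosomal, spliceosomal, signal recognition particle and mitochondrial RNAs as a set, the measured levels showed no rise shared by both strains. Their median log2 ratio was 4.77 in wild type and -0.91 under the ∆wee1 label (SD over genes 3.22). Under that label 5 of them had a ratio above 0. That does not exclude a shared response, since carry-over of tailless RNA may have differed between the pools labelled ∆wee1 and masked it. Ribosomal RNA held 10.8% of FPKM in the untreated pool of that label and 3.19% after H2O2. A shared response also stays open for 24 nucleolar, RNase P and MRP RNAs, with medians of 3.67 and 0.73 (SD 2.39). Of these 15 had a ratio above 0 under the ∆wee1 label. Carry-over of tailless RNA into the wild-type H2O2 libraries and a response to H2O2 present in wild type alone cannot be told apart, because genotype, treatment and library preparation coincide in 1 pool. Of 82 measured structural and mitochondrial RNA genes 64 (78%) had their highest FPKM in that pool, a share that either would give. It leaves out 4 measured ribosomal RNA genes listed at 0 there, which the authors' deposited table marks as having too many reads. Over 70 measured genes of these classes listed above 0 in a pool labelled ∆wee1, not chosen by their rise, the medians were 3.55 in wild type and -0.15 under the ∆wee1 label (SD 3.03), which either would give as well. Some classes also differed without H2O2. The median log2 ratio of the untreated pool labelled ∆wee1 over untreated wild type was 1.78 for spliceosomal, 0.89 for nucleolar and 0.86 for mitochondrial RNAs. For ribosomal RNAs the median was 0, though their share of FPKM was 3.13% in untreated wild type and 10.8% in the untreated pool labelled ∆wee1. That median therefore does not show that ribosomal RNA was alike in these pools. A response to H2O2 in wild type alone does not account for this untreated difference, whose cause was not tested.

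Among nuclear protein-coding genes, cmt2 had a difference of 1.47 and SPAC2H10.01 of 1.37, with adjusted p-values of the z test of 0.0150 and 0.00105. The log2 ratio of cmt2 after H2O2 was -2.50 in wild type and -1.04 under the ∆wee1 label, so its level went down by less there. That of SPAC2H10.01 was -0.86 in wild type and 0.51 under the ∆wee1 label. The ribonuclease H2 subunit gene rnh203 had a difference of -3.79 (adjusted p of the z test 0.0459). Its level was 0.0354 FPKM in untreated wild type, 10.6 in wild type after H2O2, 13.9 in the untreated pool labelled ∆wee1 and 11 in that label after H2O2.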

How the results depend on the processing

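The minimum fold, the adjustment within a single pair, the normal p, both z tests, the limit to nuclear protein-coding genes, the lists without mitochondrially encoded members and the lists at a mean of at least 5 FPKM were chosen after the data were seen. No paired analysis was possible because the values used here are 1 per group and carry no replicate number. For the same reason the linear model across libraries with or without a variance trend, fits over the groups of a single comparison, gene set tests on libraries (camera, fry) and leaving out each library were not run, nor were count models, since the values are FPKM. Depth limits the rest in an unknown way, since the number of reads behind each FPKM value is not known.

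The counts of calls in the authors' deposited table moved most with the p-value and with a minimum fold. With the normal p of the listed statistic, calls in the authors' deposited table went from 906 to 424 for H2O2 in wild type, from 598 to 233 for H2O2 under the ∆wee1 label, from 557 to 182 between untreated genotypes and from 856 to 275 between genotypes under H2O2. At least 2-fold were 322, 217, 172 and 236 of the calls of the authors' deposited table, in the same order, fewer by construction. Adjustment within a pair (909, 533, 460 and 850), a mean of at least 5 FPKM (874, 574, 522 and 811) and the limit to nuclear protein-coding genes (769, 504, 469 and 721) moved the counts of the authors' deposited table less. The 246 genes with a response difference of at least 1 became 302 with a pseudocount of 0.1 FPKM, 163 with 5 FPKM and 250 under quantile normalization. Among nuclear protein-coding genes they were 58, while the z test passed 19 and its scaled form 56.

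Quantile normalization moved the list medians most. It turned the median of chaperones after H2O2 in wild type to -0.036, of the respiratory list to -0.088 in wild type and to 0.023 for the response difference, and of ribosomal proteins between genotypes under H2O2 to 0.00. For the ribosomal protein gene rps3001 in wild type it gave -0.040. Lists outside the central 95% of random lists for the response difference went from 6 to 10 under it. The cause was not tested. Of 115 list medians it left 60 in place, against 104 under median centring, 111 with a pseudocount of 0.1 FPKM, 104 with 5 FPKM and 114 without mitochondrially encoded members, counting as in place a median that moved by less than about 1 SD of the medians of random lists. Leaving out mitochondrially encoded members could move the respiratory list alone, so most of those 114 were fixed in advance.

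Of 425 log2 ratios of named genes, 421 moved by less than 1 standard error under median centring, 401 and 368 with the low and high pseudocount and 356 under quantile normalization. Among the named ones that were called, rps3001 was the only 1 whose sign turned. Over all calls of the authors' deposited table, quantile normalization kept the sign of 895 of 906, 597 of 598, 556 of 557 and 824 of 856, in the order above. Median centring kept every sign, while another pseudocount cannot turn a sign.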

Other observations

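Every test of an explanation in this part, and the test of chromosome ends, was chosen after the results were seen. Long non-coding RNAs had higher medians than coding genes after H2O2, a difference that was not tested. Over 1147 of them the median log2 ratio was 0.28 in wild type and 0.16 in the pools labelled ∆wee1, against -0.03 and -0.03 over nuclear protein-coding genes. Between genotypes their medians were 0.07 untreated and -0.05 after H2O2. The gene prl65 (SPAC19A8.16, chromosome I, 2472433 to 2472961) rose with both factors, from 13.5 FPKM in untreated wild type to 69.9 after H2O2, and from 116 to 804 FPKM under the ∆wee1 label. On chromosome II the phosphate genes pho1 (II, 4446373 to 4449053) and pho84 (II, 4444125 to 4446200) and the gene ecl3 (II, 4441340 to 4441609) lie close together. All of them were lower under the ∆wee1 label after H2O2, where ecl3 stood at 12.1 against 80.3 FPKM, pho84 at 58.9 against 158 FPKM and pho1 at 77.3 against 308 FPKM. The transporters ght3 and str3 and the heme-binding shu1 also adjoin each other (I, 82746 to 84786, I, 88201 to 90300 and I, 85566 to 86324) and were all higher under that label, untreated and after H2O2.

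The wee1 transcript was higher in the pools labelled ∆wee1, by 0.79 (SE 0.219) untreated and 0.85 after H2O2, and the reason is open. An exchange of the genotype labels is argued against by ura4, the marker deleted from the wild-type strain, which was higher in the pools labelled ∆wee1 by 7.36 (SE 1.55) untreated and 7.78 after H2O2. An extra copy of wee1 together with its neighbours is argued against by the 10 nearest protein-coding genes, whose median log2 ratio was 0.049 (SD over genes 0.203) untreated and 0.048 (SD 0.403) after H2O2. Reads from a part of wee1 left at the disrupted locus, for example transcribed from the inserted marker, may give the same rise, and cannot be told apart from whole wee1 transcripts by 1 value per gene. A biological reading, in which the strain makes more of a wee1 transcript than wild type does, stays equally untested.

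Genes near chromosome ends differed between the genotype labels in runs. There were 6 runs of at least 3 neighbouring protein-coding genes at least 4-fold apart. The fold was taken per gene from FPKM summed over both conditions, without a pseudocount. This fold could be under 4 in a single condition, as for cmt2 untreated (59.7 against 197 FPKM) and SPAC186.07c after H2O2 (0.598 against 0.409). Genes with a mean under 1 FPKM were kept. The run of ght3 and shu1 reached 3 genes only through SPAPJ695.01c (at most 1.71 FPKM). Members such as SPAC869.09, hry1 and new22 are called in neither condition in the authors' deposited table. All 6 runs lay within 100 kb of the outermost gene of a chromosome in the coordinates of the files. That range holds 3.99% of 5138 genes. Of the runs 4 were higher in the pools labelled ∆wee1 and 2 in wild type. Within 50 kb of the ends, 17 of 51 tested genes are called in the same direction untreated and after H2O2 in the authors' deposited table, against 308 of 4895 elsewhere (two-sided Fisher's exact test, p = 9.96e-09). Neighbouring genes are not independent, so this p is too small.

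Reads shared between near-identical copies are argued against for 26 of the 27 genes in these runs (96.3%), of which less than 10% of the length matched elsewhere in assembly ASM294v3, and stay open for SPCP20C8.03, of which 49.2% matched. A stretch of chromosome missing from a strain is argued against for 1 gene, cmt2, which has no copy elsewhere and still stood at 9.69 FPKM or more in both pools of the lower label. For the other 26 genes of the 6 runs, the level left in the lower label had a median of 9.16% of that in the other (SD 5.76, from 0 to 20.8%) and reached at most 6.97 FPKM. Among them ght3 stood at 5.74 FPKM in untreated wild type and 1.92 after H2O2, and eno102 at 2.83 and 6.97. As a yardstick, ura4, which is deleted from the wild-type strain, stood under 1 FPKM there. The levels of ght3 and eno102 lie above that, while new22 is listed at 0 in both pools of the lower label. Since 1 deleted gene sets the yardstick and the runs mix such levels, the 26 genes as a set do not decide. A missing stretch and silencing of an intact stretch were not told apart for them. A difference in silencing near chromosome ends between the strains is a hypothesis that these values leave open, and whether it goes with the ∆wee1 label or with other differences between the strains was not tested.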
